A study of Rattus norvegicus with 11 samples.

How the data were processed

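Total RNA was extracted from rat small intestine with Trizol and turned into biotin-labelled cRNA for an Affymetrix rat array, per the labels' protocols. The table used here holds log2 values per probe set and array, normalized by the authors with a method that is not given in the sources used here. That the values are log2 was read from their range, since no label states it: the lowest values per array were 5.36 to 5.52 and the highest 14.22 to 14.48. Median values per array were 7.886 to 7.933. Software, background correction, filters, scan dates and batches are not given in the sources used here. Probe sets carry Entrez gene numbers, 1 probe set per gene, so the probes had been regrouped by gene before the values were made. Of 11484 probe sets, 57 controls were left out of the tests and 11427 were tested with no filter on level. A symbol was given for 11018 of these and 409 had none here. The Entrez numbers of 10996 were found in the reference table of gene names, and 0 symbols changed. Probe sets of gene families with nearly identical copies, such as Mcpt1, Ugt2b7 and the Reg genes, may measure more than 1 copy.

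Arrays were grouped by their titles as NBD (3), BD (4) and BD_VNS (4). The source entry of the NBD samples also mentions brain-dead animals, and the titles were followed. No array was left out, except in alternatives named below. Before the data were examined, the groups, the comparisons, the gene lists, the tests, the rule for naming genes and most alternatives were fixed. The 3 groups were fitted together with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), each pair of groups was compared, and p was adjusted by Benjamini and Hochberg over all probe sets. A gene passed at an adjusted p under 0.05. Of 1030 genes in 42 lists, 772 were measured, and each list had at least 5 measured genes. Lists were tested with camera in limma at a preset correlation of 0.01, with p adjusted over the 42 lists. The same test with a correlation estimated for each list, and fry, were the alternatives. "Adjusted over the list alone" means that p was adjusted among the measured members of that list. Changes are given with the moderated standard error (SE) and group means with the standard deviation (SD).

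Genes were named by this rule: the 10 largest rises and 10 largest falls among genes that passed and whose arrays did not overlap between the groups; a fixed set of inflammatory genes; and up to 4 members with the smallest p of each list described. Genes without a symbol and predicted genes were not named. Rankings of the 10 largest rises or falls below are among genes that meet this rule. Exact permutation p values came from all arrangements of the arrays. The 3' to 5' ratio is the mean over the Gapdh and Actb control probe sets of the difference in log2 level between the 3' and the 5' probe set.

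Alternatives fixed before the data were examined were eBayes with a trend and robust variance, quantile normalization, median centring, leaving out the lowest 25% or 50% of probe sets by level, only the 2 groups compared, array weights, replicate numbers as a block, an adjusted p under 0.10, an absolute log2 fold change of at least 1, 1 probe set per named gene, the 3' to 5' ratio as a covariate, and leaving out each array in turn. Alternatives chosen after seeing the data were to leave out BD 4 and BD 6, to use the mean level of pancreatic acinar genes as a covariate, and to use the 3' to 5' ratio as a covariate without BD 4 and BD 6. The correlation between changes without BD 4 and BD 6, its simulated values, and the counts of opposite signs with the BD arrays split, were also chosen after seeing the data.

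The fits were tested on simulated data, in 10 draws with 200 of 11427 genes changed. Changes of 0.5 log2 units were found for 92.1% of genes in BD against NBD, 94.7% in BD_VNS against BD and 90.6% in BD_VNS against NBD, with 10.1, 11.5 and 8.4 false calls per draw. With the covariate these shares were 90.6%, 88.9% and 75%. A list of 20 genes shifted by 0.5 log2 units was found in 10 of 10 draws in each comparison by camera with either correlation. Simulated genes were drawn independently of each other. These draws therefore do not show how either setting performs on lists whose members correlate.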

Results

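Gene expression was measured in the small intestine of rats with 1 Affymetrix array per sample, 11 arrays in all. Of these, 3 came from ventilated rats without brain death (NBD, replicates 1, 3 and 4), 4 from brain-dead rats (BD, replicates 1, 3, 4 and 6) and 4 from brain-dead rats whose vagus nerve was stimulated (BD_VNS, replicates 1 to 4), with tissue taken at 6 hours. The vagus nerve carries parasympathetic fibres to the gut, and its stimulation dampens cytokine release in several models of inflammation. The labels do not say whether each array comes from a separate animal, and they call the rats transgenic without naming a gene. After control probe sets were left out, 11427 probe sets, each for 1 gene, were compared. The mean log2 level per array ran from 8.169 to 8.178. The number of arrays limits the precision of every value below.

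Transcripts of the exocrine pancreas set 2 BD arrays apart from the rest. The mean log2 level of 18 digestive enzyme and acinar cell genes was 13.7 in BD 4 and 13.1 in BD 6, against 7.13 to 7.84 in the other 9 arrays. Cpa1, a pancreatic carboxypeptidase, was at 13.99 in BD 4 and 13.40 in BD 6 and averaged 6.56 in the other 9 arrays. In those 9 arrays 2 of the 18 genes lay above the median probe set, so the sizes of these differences are bounds at most. Within the other 9 arrays, BD_VNS 3 and BD_VNS 4 had the highest list means, 7.84 and 7.69, and 15 of the 18 members were higher in both than in all of the remaining 7 arrays. A sign of RNA quality, the log2 ratio of 3' to 5' signal of the Gapdh and Actb control probe sets, was 0.76 ± 0.09 in NBD (SD, n = 3), 0.84 ± 0.05 in BD (SD, n = 4) and 0.98 ± 0.15 in BD_VNS (SD, n = 4). Its 2-sided exact permutation p was 0.229 for BD against NBD, 0.143 for BD_VNS against BD and 0.0857 for BD_VNS against NBD, where the smallest p that the arrangements allow is 0.0286. Among the BD_VNS arrays the ratio was 0.75 in BD_VNS 2 and 1.03 to 1.10 in the other 3.

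**Figure D1:**
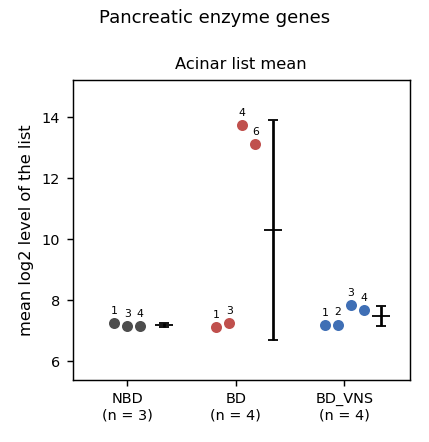
Mean log2 level of 18 pancreatic acinar genes in each array, with replicate numbers above the points and bars for the group mean ± SD. BD 4 and BD 6 lie at 13.7 and 13.1, and the other 9 arrays between 7.13 and 7.84.

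The comparison of BD with NBD asked how brain death changed expression in the intestine. The largest falls were those of Fkbp5 and Sgk1, which glucocorticoids induce. Fkbp5 (Entrez Gene 361810), a co-chaperone of the glucocorticoid receptor, fell from 9.79 ± 0.40 (SD, n = 3) in NBD to 7.16 ± 0.10 (SD, n = 4) in BD, which is 6.2-fold lower (log2 fold change -2.63 ± 0.14, SE; adjusted p = 1.25e-06). Sgk1 (Entrez Gene 29517), a kinase that regulates sodium transport, fell from 12.48 ± 0.08 to 10.22 ± 0.24 and was 4.82-fold lower (adjusted p = 1.25e-06). Some inflammatory genes rose. Ccl2 (Entrez Gene 24770), a chemokine that attracts monocytes, rose from 7.72 ± 0.16 to 9.38 ± 0.27, a 3.17-fold higher level (adjusted p = 0.000117). Il1b (Entrez Gene 24494), the cytokine interleukin-1 beta, rose by 0.71 ± 0.07 log2 units (SE; adjusted p = 0.000165).

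Of 20 measured glucocorticoid-induced genes, 7 fell and 1 rose, and 12 did not pass. Adjusted over the list alone, 10 fell and 2 rose. The median log2 fold change of the list was -0.22 (camera, adjusted p = 3.14e-06), and the call held with an estimated correlation (adjusted p = 0.0184). Besides Fkbp5 and Sgk1, the list included Pdk4, a kinase that restrains glucose oxidation (-1.18 ± 0.08, SE), and Klf9, a transcription factor (-0.66 ± 0.05). With BD 4 and BD 6, the 2 arrays with pancreatic transcripts, left out, 7 members fell and the median was -0.28.

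**Figure D2:**
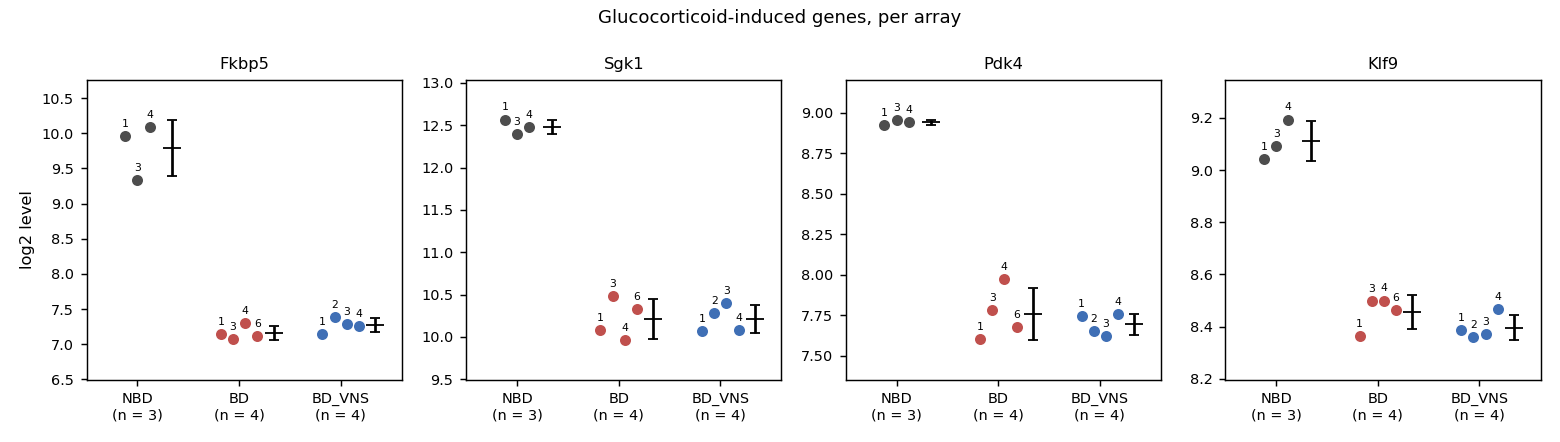
Log2 level of Fkbp5, Sgk1, Pdk4 and Klf9 in each array, with replicate numbers above the points and bars for the group mean ± SD. Each NBD array (n = 3) lies above each BD and BD_VNS array (n = 4 each) for all 4 genes; Fkbp5 averages 9.79 in NBD, 7.16 in BD and 7.27 in BD_VNS.

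Of 36 cytokine and chemokine genes, 9 rose and 1 fell (adjusted over the list alone, 13 and 2), with a camera adjusted p of 3.28e-05 that was lost with an estimated correlation (adjusted p = 0.393). The members included Ccl2, Il1b, Cxcl1 (0.53 ± 0.12, SE), a neutrophil chemokine, and Ccl11 (0.83 ± 0.15), which attracts eosinophils. Cxcl11, an interferon-induced chemokine, fell by 0.55. Among 20 targets and feedback regulators of NF-kB, 6 rose and 1 fell (adjusted over the list alone, 8 and 2; camera adjusted p = 7.19e-05, and adjusted p = 0.378 with an estimated correlation). Bcl3 rose by 0.52 ± 0.08 and Tnip1, an inhibitor of NF-kB signalling, fell by 0.48. Of 13 adhesion molecules, Icam1, which binds leukocytes on endothelium, rose (0.70 ± 0.12), and it was also the 1 call adjusted over the list alone (camera adjusted p = 0.00374, and adjusted p = 0.505 with an estimated correlation). Of 23 interferon response genes, 4 rose and 1 fell (adjusted over the list alone, 7 and 3; camera adjusted p = 0.0254, and adjusted p = 0.535 with an estimated correlation), among them Gbp2 (0.57 ± 0.09) and Irf1 (0.51 ± 0.09). With BD 4 and BD 6 left out, and so with fewer arrays, 3 cytokine genes, 3 NF-kB targets and 2 interferon response genes rose, while the list medians went from 0.10 to 0.11, from 0.15 to 0.17 and from 0.11 to 0.07.

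Of the other inflammatory genes fixed for every comparison, Hmox1, which degrades heme, rose by 0.71 ± 0.11 (SE; adjusted p = 0.00313) and Socs3, a brake on cytokine signalling, rose by 0.33 ± 0.07 (adjusted p = 0.0186). Il6 (0.11, adjusted p = 0.191), Tnf (0.14, adjusted p = 0.0727), Vcam1 (0.41, adjusted p = 0.0937) and Nfkbia (-0.33, adjusted p = 0.105) did not pass. Neither did Il10, Cxcl2, Sele, Selp and Ptgs2, whose adjusted p ran from 0.49 to 0.942. Nos2 and Chrna7 had no named probe set.

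Some genes of absorption fell. Of 23 enterocyte genes, 8 fell and 0 rose (adjusted over the list alone, 13 and 1; median -0.24; camera adjusted p = 1.35e-05, and adjusted p = 0.505 with an estimated correlation). They included Ada, adenosine deaminase (-0.66 ± 0.08, SE), and Apob, the protein of chylomicrons (-0.54 ± 0.08). Of 30 nutrient and ion transporters, 9 fell and 1 rose (adjusted over the list alone, 14 and 2; camera adjusted p = 6.66e-05, and adjusted p = 0.378 with an estimated correlation). Members included the nucleoside transporter Slc28a2 (-1.23 ± 0.15) and the amino acid transporter subunit Slc3a2 (-0.68 ± 0.09). Of 26 genes of xenobiotic metabolism, 6 fell and 1 rose (adjusted over the list alone, 7 and 1; camera adjusted p = 0.000124, and adjusted p = 0.378 with an estimated correlation). Members included the cytochrome Cyp3a9 (-0.63 ± 0.06). Enterocyte genes averaged 0.11 log2 units lower in BD 4 and BD 6 than in BD 1 and BD 3, and without BD 4 and BD 6 3 of the 23 fell, as did 5 transporter genes and 2 genes of xenobiotic metabolism, with medians of -0.16, -0.19 and -0.11 (-0.24, -0.24 and -0.12 with all arrays).

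Some genes of smooth muscle and matrix rose. Of 19 smooth muscle genes 3 rose and 0 fell (adjusted over the list alone, 6 and 0; camera adjusted p = 1.02e-05, and adjusted p = 0.611 with an estimated correlation). Members included the contractile protein gene Cnn1 (0.60 ± 0.12, SE) and the small heat shock protein gene Hspb6 (0.59 ± 0.13). Of 31 fibroblast and matrix genes 3 rose and 0 fell (adjusted over the list alone, 6 and 0; camera adjusted p = 0.000116, and adjusted p = 0.664 with an estimated correlation). Members included the collagen genes Col3a1 (0.65 ± 0.14) and Col5a2 (0.37 ± 0.09). Without BD 4 and BD 6, 2 smooth muscle genes and 0 matrix genes rose, while the medians went from 0.18 to 0.28 and from 0.16 to 0.17; in the full data, 9 of the 31 matrix genes had an unadjusted limma p under 0.05.

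The 10 largest rises were, from the top, Reg1a (2.01 ± 0.39, SE), Slc11a2 (1.98 ± 0.25), Reg3g (1.83 ± 0.47), Ccl2, Nadk2 (1.04 ± 0.23), Efna1 (1.03 ± 0.19), Ugt2b7 (1.01 ± 0.24), Egr1 (0.84 ± 0.19), Ccl11 and Mpv17 (0.77 ± 0.13). Slc11a2 (Entrez Gene 25715) takes up iron at the brush border, Reg3g is an antibacterial lectin, Egr1 is an immediate early transcription factor, and Reg1a is made in large amounts by the exocrine pancreas. The level of Reg1a was 13.42 in BD 4 and 12.64 in BD 6, the arrays with pancreatic transcripts, and averaged 10.98 in the other 9 arrays. The 10 largest falls were Fkbp5, Sgk1, Noct (-1.69 ± 0.13), the sugar-phosphate exchanger Slc37a2 (-1.66 ± 0.09), Tmem86a (-1.60 ± 0.24), Cipc, a repressor of the clock protein CLOCK (-1.54 ± 0.10), the sulfotransferase Sult1a1 (-1.49 ± 0.14), Cubn, a vitamin B12 receptor subunit (-1.45 ± 0.36), the lactate transporter Slc5a12 (-1.43 ± 0.15) and the carbonic anhydrase Car4 (-1.37 ± 0.36). In total 655 genes passed, 240 higher and 415 lower in BD, of which 9 rises and 21 falls reached 2-fold. Camera passed 16 of 42 gene lists, 10 upward and 6 downward, and the glucocorticoid list alone held with an estimated correlation.

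Without BD 4 and BD 6 the count was 293, and it was 393 without BD 6, 332 without NBD 1, 317 without NBD 3 and 400 without NBD 4. Of 48 genes named in this comparison that passed, 35 passed in all 11 fits that left out 1 array. The call was lost in at least 1 of these fits for Reg3g (adjusted p 0.00446 to 0.196 over 24 alternative fits), Cubn (0.00262 to 0.178 over 23), Car4 (0.00644 to 0.204), Col5a2 (0.00767 to 0.171), Cxcl1 (0.00566 to 0.141 over 22), Ugt2b7 (0.00239 to 0.144), Nadk2 (0.00197 to 0.112), Egr1 (0.00144 to 0.117), Hspb6 (0.00149 to 0.118), Col3a1 (0.00443 to 0.0944), Socs3 (0.00455 to 0.111 over 23), Cnn1 (0.000852 to 0.0646, without NBD 1 or NBD 3) and Reg1a (0.000695 to 0.0865, without NBD 3 or NBD 4).

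The comparison of BD_VNS with BD asked how vagus nerve stimulation changed expression in brain-dead rats. Several inflammatory genes fell. Ccl2 was 8.28 ± 0.26 (SD, n = 4) in BD_VNS and 9.38 ± 0.27 (SD, n = 4) in BD, a 2.15-fold lower level (log2 fold change -1.10 ± 0.15, SE; adjusted p = 0.00397). Il1b was 8.17 ± 0.12 in BD_VNS and 8.87 ± 0.08 in BD (-0.70 ± 0.07, SE; adjusted p = 0.000933), and in NBD it was 8.16 ± 0.10 (SD, n = 3). Ccl11 fell by 1.19 (adjusted p = 0.00188) and Icam1 fell by 0.61 (adjusted p = 0.0111). Of gene lists for cell types, 14 of 17 macrophage genes, 21 of 31 matrix genes and 5 of 14 mast cell genes fell, and 6 of 23 enterocyte genes rose; with an estimated correlation none of these lists passed (adjusted p = 0.0982, 0.0982, 0.143 and 0.222).

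**Figure D3:**
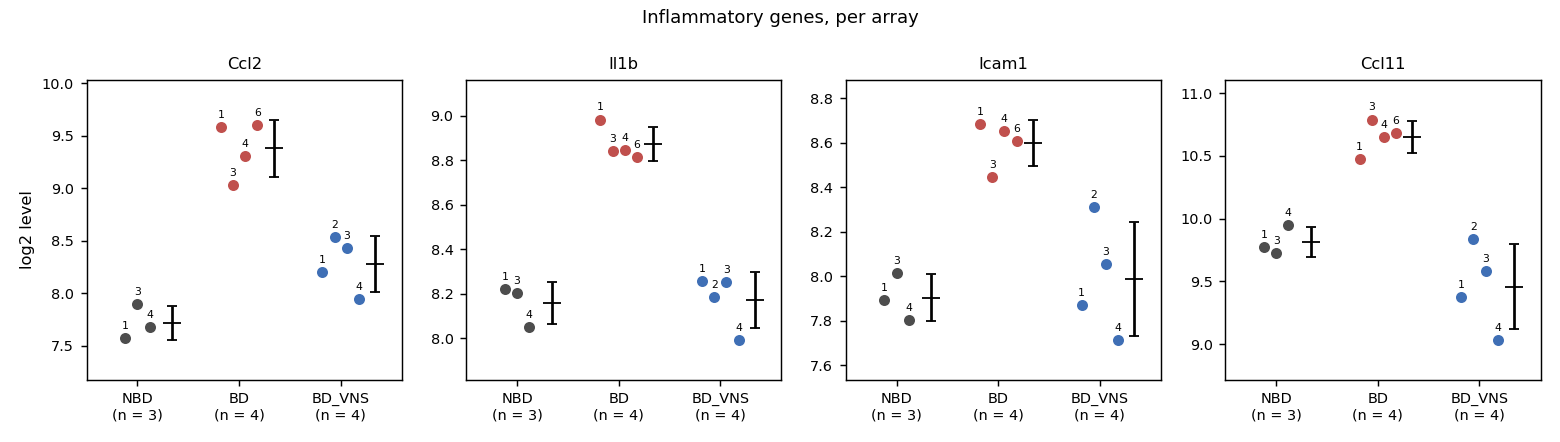
Log2 level of Ccl2, Il1b, Icam1 and Ccl11 in each array, with replicate numbers above the points and bars for the group mean ± SD (NBD n = 3, BD and BD_VNS n = 4). Each BD array lies above each NBD and BD_VNS array for all 4 genes; Il1b averages 8.16 in NBD, 8.87 in BD and 8.17 in BD_VNS.

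Of 36 cytokine and chemokine genes, 11 fell and 0 rose (adjusted over the list alone, 15 and 0; camera adjusted p = 1.03e-08, and adjusted p = 0.0982 with an estimated correlation). Cxcl12, which retains leukocytes in tissue, fell by 0.62. Of 13 adhesion molecules, 5 fell and 0 rose (adjusted over the list alone, 10 and 0; camera adjusted p = 1.4e-07, and adjusted p = 0.0982 with an estimated correlation). Members included Icam2 (-0.41 ± 0.07, SE) and Jam2 (-0.26 ± 0.05). Of 20 NF-kB targets 3 fell and 0 rose (adjusted over the list alone, 5 and 0; camera adjusted p = 1.51e-06, and adjusted p = 0.0982 with an estimated correlation). Members included the anti-apoptotic gene Bcl2a1 (-0.85 ± 0.11) and the kinase gene Map3k8 (-0.40 ± 0.07). Of 23 interferon response genes 7 fell and 0 rose (adjusted over the list alone, 7 and 1; camera adjusted p = 0.000448, and adjusted p = 0.143 with an estimated correlation), among them Gbp2 (-0.73 ± 0.08). Vcam1 (-0.55 ± 0.12, adjusted p = 0.024) and Cxcl1 (-0.55 ± 0.11, adjusted p = 0.0195) also fell, though single arrays of the groups overlapped for both. With the 3' to 5' ratio as a covariate, 5 cytokine genes, 3 adhesion genes, 3 NF-kB targets and 4 interferon response genes fell, and without BD 4 and BD 6 the counts were 5, 2, 1 and 2. The list medians, in that order, were -0.09, -0.21, -0.12 and -0.08 at first, -0.09, -0.18, -0.16 and -0.13 with the covariate, and -0.07, -0.30, -0.13 and -0.05 without these arrays. Il6 (-0.05, adjusted p = 0.51), Tnf (-0.03, adjusted p = 0.627), Ptgs2 (-0.15, adjusted p = 0.0882), Hmox1 (-0.18, adjusted p = 0.317), Nfkbia (-0.33, adjusted p = 0.075) and Socs3 (-0.20, adjusted p = 0.0914) did not pass. Il10, Cxcl2, Sele and Selp did not pass either, and their adjusted p ran from 0.551 to 0.937.

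Of 17 macrophage and monocyte genes, 14 fell and 0 rose (adjusted over the list alone, 15 and 0; median -0.58; camera adjusted p = 1.15e-17, and adjusted p = 0.0982 with an estimated correlation). They included Tyrobp, a signalling adaptor of myeloid cells (-0.89 ± 0.09, SE), and Csf1r, the receptor of macrophage growth factor (-0.77 ± 0.12). Of 31 fibroblast and matrix genes, 21 fell and 0 rose (adjusted over the list alone, 28 and 0; median -0.48; camera adjusted p = 1.07e-25, and adjusted p = 0.0982 with an estimated correlation), with Mgp (-0.97 ± 0.11), Col5a2 (-0.73 ± 0.09) and Col3a1 (-0.86 ± 0.13) among them. Of 14 mast cell genes, 5 fell and 0 rose (adjusted over the list alone, 6 and 0; camera adjusted p = 9.22e-07, and adjusted p = 0.143 with an estimated correlation). Members included Mcpt10 (-1.04 ± 0.12) and the IgE receptor subunit Fcer1a (-0.49 ± 0.06). Of 17 goblet and Paneth cell genes, 3 fell and 0 rose (adjusted over the list alone, 7 and 0; camera adjusted p = 1.63e-05, and adjusted p = 0.193 with an estimated correlation). Members included the mucus proteins Zg16 (-0.85 ± 0.13) and Tff3 (-0.55 ± 0.10). Other lists that camera passed downward included endothelial genes (3 of 19 fell, and 12 adjusted over the list alone) and T and NK cell genes (2 of 23, and 8). B and plasma cell genes (2 of 10, and 6) and MHC class II genes (1 of 8, and 6) passed as well. In that order, the camera adjusted p were 7.79e-08, 9.22e-07, 8.89e-06 and 9.98e-05. With an estimated correlation the adjusted p were 0.143, 0.222, 0.208 and 0.251. With the 3' to 5' ratio as a covariate 2, 2, 0 and 0 members fell with limma, and the medians went from -0.15 to -0.13, from -0.22 to -0.10, from -0.37 to -0.23 and from -0.31 to -0.13.

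Fewer genes of these lists passed in other fits. With the 3' to 5' ratio as a covariate, 8 macrophage genes, 11 matrix genes, 4 mast cell genes and 2 goblet and Paneth cell genes fell, and with BD 4 and BD 6 left out the counts were 7, 5, 3 and 3, with 1 matrix gene higher. The medians were -0.58, -0.48, -0.13 and -0.31 at first, -0.53, -0.39, -0.08 and -0.22 with the covariate, and -0.66, -0.51, -0.15 and -0.45 without both arrays. The macrophage list averaged 8.63 in BD_VNS 2, against a group mean of 8.37 ± 0.20 (SD, n = 4) in BD_VNS and 8.96 ± 0.06 (SD, n = 4) in BD. Of 19 smooth muscle genes 0 passed with limma in either direction and 0 had an unadjusted p under 0.05 (median -0.004, and 0.005 with each array centred on its median). The smooth muscle median was -0.10 with the covariate and -0.11 without BD 4 and BD 6, where camera passed the list downward (adjusted p = 0.00243, and adjusted p = 0.443 with an estimated correlation). Of 24 genes of enteric neurons and glia 0 passed and 2 had an unadjusted p under 0.05 (median 0.06), and of 24 cholinergic and adrenergic genes 0 passed and 3 had an unadjusted p under 0.05 (median 0.05). Of the cholinergic and adrenergic genes, 21 had a positive change (camera adjusted p = 0.12). Without BD 4 and BD 6 their median was 0.08 and camera passed the list upward (adjusted p = 0.00367, and adjusted p = 0.316 with an estimated correlation).

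**Figure D4:**
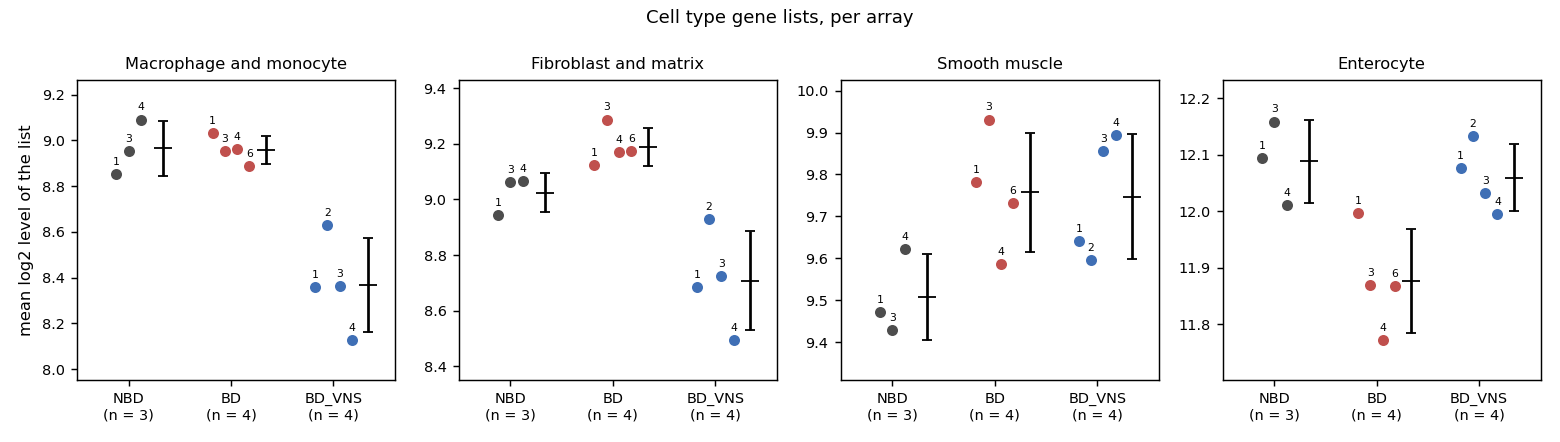
Mean log2 level of 4 cell type gene lists in each array, with replicate numbers above the points and bars for the group mean ± SD (NBD n = 3, BD and BD_VNS n = 4). The macrophage list averages 8.97 in NBD, 8.96 in BD and 8.37 in BD_VNS, and the smooth muscle list 9.51, 9.76 and 9.75.

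Of 23 enterocyte genes, 6 rose and 0 fell (adjusted over the list alone, 12 and 0; median 0.20; camera adjusted p = 1.01e-05, and adjusted p = 0.222 with an estimated correlation), among them the peptidase Anpep (0.36 ± 0.07, SE) and the glucose transporter Slc2a2 (0.21 ± 0.04). Without BD 4 and BD 6, 0 of the 23 passed with limma, with a median of 0.12. Glucocorticoid-induced genes stayed near their BD level. The change was 0.11 for Fkbp5 (adjusted p = 0.661) and -0.01 for Sgk1 (adjusted p = 0.976). Of 20 members 2 fell (adjusted over the list alone, 3; median -0.007, and 0.003 with each array centred on its median; camera adjusted p = 0.0486, and adjusted p = 0.143 with an estimated correlation). The 1 with the smaller p, Anxa1 (-0.95 ± 0.16), is an anti-inflammatory protein of myeloid and epithelial cells.

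The 10 largest falls were Clu (-2.40 ± 0.58, SE), Mcpt1 (-1.84 ± 0.36), Reg1a (-1.56 ± 0.36), Cpa3 (-1.51 ± 0.21), Ccl11 (-1.19 ± 0.14), Ifitm3 (-1.13 ± 0.22), C1qc (-1.11 ± 0.20), Ccl2, Ctsl (-1.09 ± 0.19) and Cd53 (-1.09 ± 0.20). Mcpt1 and Cpa3 are mast cell proteases, C1qc is a complement subunit made by macrophages, and Clu is a secreted chaperone. The level of Clu was 12.48 in BD 4 and 11.64 in BD 6, the arrays with pancreatic transcripts, and 10.35 and 8.81 in BD 1 and BD 3. Reg1a, a member of the acinar list, was at 13.42 in BD 4 and 12.64 in BD 6 and averaged 10.98 in the other 9 arrays. Without BD 4 and BD 6 its fall did not pass (limma adjusted p = 0.166). Among genes whose arrays did not overlap between the groups, the 10 largest rises were small. First came the amino acid transporter gene Slc16a10 (0.39 ± 0.10), the Wnt target Axin2 (0.39 ± 0.09) and the fructose transporter gene Slc2a5 (0.39 ± 0.09). Next were Hpdl (0.38 ± 0.06), Abhd6 (0.37 ± 0.06), Anpep, Ldb3 (0.35 ± 0.07), Ppp1r1b (0.34 ± 0.07), Ppargc1b (0.33 ± 0.07) and Chdh (0.33 ± 0.07). Cyp4b1 rose more (0.51, limma adjusted p = 0.0395), but its arrays overlapped. In total 635 genes passed, 217 higher and 418 lower in BD_VNS, of which 0 rises and 16 falls reached 2-fold. With quantile normalization 784 passed, 361 higher and 423 lower. Camera passed 26 of 42 lists, 5 upward and 21 downward. With an estimated correlation 0 held and 14 had an unadjusted p under 0.05. The 21 include the pancreatic acinar list (median -2.98), which without BD 4 and BD 6 passed upward instead (median 0.28). They also include lists not described above: antimicrobial, immediate early, endoplasmic reticulum stress, prostaglandin and vasoactive, coagulation, apoptosis and JAK-STAT genes. The test fry, which asks whether a list itself moves 1 way, passed 19.

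Without BD 4 and BD 6 the count was 152, with the 3' to 5' ratio as a covariate 415, and it was 298 without BD 6, 376 without BD_VNS 1, 1108 without BD_VNS 2, 355 without BD_VNS 3 and 279 without BD_VNS 4. Of 43 genes named in this comparison that passed, 22 also passed without BD 4 and BD 6 and 33 passed in all 11 fits that left out 1 array. The others were Clu (adjusted p 0.00649 to 0.18 over 24 alternative fits), Reg1a (0.00755 to 0.171), Slc16a10 (0.0158 to 0.198), Vcam1 (0.00304 to 0.195), Ldb3 (0.00146 to 0.234), Slc2a5 (0.015 to 0.175), Ppp1r1b (0.00293 to 0.217), Chdh (0.0072 to 0.108), Axin2 (0.00529 to 0.0851) and Cxcl1 (0.0125 to 0.133 over 22).

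The comparison of BD_VNS with NBD asked how far stimulated brain-dead rats stood from ventilated controls. The largest falls were again those of Fkbp5 and Sgk1. Fkbp5 was 7.27 ± 0.10 (SD, n = 4) in BD_VNS and 9.79 ± 0.40 (SD, n = 3) in NBD, 5.74-fold lower (log2 fold change -2.52 ± 0.14, SE; adjusted p = 2.47e-06). Sgk1 was 4.85-fold lower (adjusted p = 1.9e-06). Slc11a2, the iron transporter gene, was 4.88-fold higher (2.29 ± 0.25; adjusted p = 0.000334). Il1b, Icam1 and Cxcl1, which fell in BD_VNS against BD, did not pass here: the difference was 0.01 ± 0.07 for Il1b (adjusted p = 0.944), 0.08 ± 0.12 for Icam1 (adjusted p = 0.746) and -0.02 ± 0.12 for Cxcl1 (adjusted p = 0.964). Ccl2 and Hmox1 were above the control level (adjusted p = 0.0499 and 0.0141) and Nfkbia was below it (adjusted p = 0.00363).

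Of 20 glucocorticoid-induced genes, 10 fell and 2 rose (adjusted over the list alone, 12 and 2; median -0.46; camera adjusted p = 2.69e-10), and the call held with an estimated correlation (adjusted p = 0.00322). Pdk4 (-1.25 ± 0.08, SE) and Klf9 (-0.71 ± 0.05) were among them, and with the 3' to 5' ratio as a covariate 7 fell and the median was -0.32. Of 17 macrophage and monocyte genes, 12 fell and 0 rose (adjusted over the list alone, 13 and 0; median -0.64; camera adjusted p = 8.63e-13, and adjusted p = 0.246 with an estimated correlation). Members included Tyrobp (-0.70 ± 0.10) and the antibody receptor gene Fcgr2b (-0.97 ± 0.15). Of 31 fibroblast and matrix genes, 9 fell and 0 rose (adjusted over the list alone, 17 and 0; median -0.28; camera adjusted p = 3.02e-10, and adjusted p = 0.413 with an estimated correlation). Members included Mgp (-1.09 ± 0.11) and the proteoglycan gene Dcn (-1.16 ± 0.19). Of 14 mast cell genes 5 fell and 0 rose (adjusted over the list alone, 6 and 0; camera adjusted p = 0.000533, and adjusted p = 0.444 with an estimated correlation), Mcpt10 among them (-0.71 ± 0.13). With the covariate, 3 macrophage genes, 2 matrix genes and 0 mast cell genes fell, and the medians went from -0.64 to -0.40, from -0.28 to -0.13 and from -0.13 to -0.04; in the fit without it, 6 of the 14 mast cell genes had an unadjusted limma p under 0.05.

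Of 25 cell cycle genes, 4 rose and 0 fell (adjusted over the list alone, 5 and 0; median 0.14; camera adjusted p = 1e-05, and adjusted p = 0.413 with an estimated correlation), among them Ccnd1, a cyclin of the start of the cycle (0.63 ± 0.08, SE), and Kif20a, a kinesin of cell division (0.25 ± 0.05). With the 3' to 5' ratio as a covariate 2 cell cycle genes rose, and the list median was 0.196. Of 36 cytokine and chemokine genes, 2 rose and 3 fell (adjusted over the list alone, 2 and 3, with a camera adjusted p of 0.334). Ccl2 was 0.56 ± 0.16 above the control level (adjusted p = 0.0499) and Hmox1 0.52 ± 0.11 (adjusted p = 0.0141), and Nfkbia, the inhibitor of NF-kB, fell by 0.66 (adjusted p = 0.00363). Il6, Tnf, Il10, Cxcl2, Vcam1, Sele, Selp, Ptgs2 and Socs3 did not pass, with adjusted p from 0.147 to 0.919. Of 23 enterocyte genes, 1 rose and 1 fell (adjusted over the list alone, 3 and 2; camera adjusted p = 0.656).

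The largest rises after Slc11a2 were Nadk2 (1.23 ± 0.23, SE), Ugt2b7 (1.20 ± 0.24), Efna1 (1.15 ± 0.19), Mmd (1.01 ± 0.16), Nfe2l2, the transcription factor of the antioxidant response (0.78 ± 0.11), Egr1 (0.76 ± 0.19), Mpv17 (0.73 ± 0.13), Ankh (0.73 ± 0.16) and Adh7 (0.72 ± 0.12). The largest falls after Fkbp5 and Sgk1 were Mcpt1 (-1.82 ± 0.39), Noct (-1.43 ± 0.13), Slc37a2 (-1.41 ± 0.09), Car3 (-1.38 ± 0.38), Slc28a2 (-1.36 ± 0.15), Sult1a1 (-1.32 ± 0.14), Tmem86a (-1.30 ± 0.24) and Cpa3 (-1.30 ± 0.23). In total 965 genes passed, 416 higher and 549 lower in BD_VNS, of which 6 rises and 25 falls reached 2-fold. Camera passed 20 of 42 lists, 4 upward and 16 downward, and the glucocorticoid list alone held with an estimated correlation.

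With the 3' to 5' ratio as a covariate the count was 363, and it was 494 without NBD 1, 508 without NBD 3, 591 without NBD 4, 1638 without BD_VNS 2 and 570 without BD_VNS 4. Of 43 genes named in this comparison that passed, 27 also passed with the covariate and 35 passed in all 11 fits that left out 1 array. The others were Ccl2 (adjusted p 0.0202 to 0.181 over 24 alternative fits), Car3 (1.31e-07 to 0.141 over 23), Egr1 (0.00557 to 0.246), Ugt2b7 (0.000648 to 0.149, without NBD 3), Ankh (0.00522 to 0.0869, without NBD 4), Mcpt1 (0.000404 to 0.185, without NBD 4), Hmox1 (0.00311 to 0.171, without NBD 1) and the clock gene Per2 (0.00432 to 0.0727, without NBD 1).

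The changes with brain death and with stimulation were compared gene by gene. Of 633 named genes that passed in BD against NBD, 471 (74.4%) had the opposite sign in BD_VNS against BD, 85 passed there with the opposite sign and 7 passed with the same sign. The 4 BD arrays enter both comparisons with opposite signs, so opposite signs arise with no effect of stimulation. With different BD arrays in each comparison, 2 and 2, the share with the opposite sign was 58.7% to 74.4% over 6 splits, which share arrays; 5 to 36 genes passed with the opposite sign and 0 to 6 with the same sign. Among all genes tested and with all arrays, 50 rose in BD against NBD and fell in BD_VNS against BD, and 40 did the reverse. With the BD arrays split these counts were 5 to 15 and 0 to 24, the second 0 in 2 of the 6 splits. Independent lists would share 8.78 and 7.88, values that leave out the shared arrays. Simulated unchanged groups shared 0, but with no group differing few genes pass at all, so that value is no benchmark. Across genes, which are not independent replicates, the log2 fold changes of these comparisons had a correlation of -0.69 and a covariance of -0.0318. A negative value arises from the shared BD arrays with no effect: simulated unchanged groups gave a mean of -0.46 (-0.63 to -0.25 over 100 draws) and a covariance of -0.0059. These draws took each gene independently, so the joint shift of pancreatic transcripts in BD 4 and BD 6 is not in them. A value beyond their range therefore does not show a reversal by stimulation. With the BD arrays split, the mean correlation was -0.41 (-0.64 to -0.01 over 6 splits) and the covariance -0.0203. Some of these splits placed BD 4 and BD 6 in different comparisons. Their pancreatic transcripts then enter the changes with opposite signs, which gives negative values with no effect of stimulation. How much of the mean comes from this was not tested, so the mean does not show a reversal by stimulation. With BD 4 and BD 6 left out the correlation was -0.43 and the covariance -0.011. Unchanged groups simulated for that design gave -0.64 (-0.67 to -0.59) and a covariance of -0.0054 (-0.0062 to -0.0048) with the spread of the 9 arrays, and -0.63 (-0.78 to -0.44) and -0.0119 (-0.0186 to -0.0066) with the spread of all 11. The observed correlation was less negative than in any of these draws. The observed covariance was more negative than with the spread of the 9 arrays, and within the range with the spread of all 11. With BD 1 alone in the first comparison and BD 3 alone in the second, or the reverse, the correlations were -0.30 and -0.11.

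Other genes kept their distance from the controls in both groups of brain-dead rats. Between BD against NBD and BD_VNS against NBD, 115 genes rose in both and 255 fell in both, Fkbp5, Sgk1 and Slc11a2 among them. Independent lists would share 8.74 and 19.9, values that leave out the shared controls. Simulated unchanged groups against the same controls shared 0.01 on average. With no group differing few genes pass at all, so that value is no benchmark for the shared counts. Both comparisons use the same 3 NBD arrays, which cannot be split with 2 in each part, and part of the excess may come from these shared controls.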

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

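The tests for single arrays standing apart were fixed before the result was seen, but the genes they covered were those named in the text. Each asked whether 1 array of a group of 4 lay far from the other 3 for its range. Of 300 groups tested, 9 stood apart, and chance alone gives about 1 in 20, or 15, so single cases may be chance. BD 1 stood apart for the mean level of adhesion molecules, 8.203 against 8.092 to 8.103 in the other 3 BD arrays. It also did so for B and plasma cell genes, 8.063 against 7.519 to 7.545, and for Cd53, a leukocyte surface protein, 9.856 against 9.319 to 9.379. BD 4, which holds pancreatic transcripts, stood apart for genes of endoplasmic reticulum stress, 9.892 against 9.74 to 9.753. BD_VNS 4 had the highest Egr1, 10.102 against 9.21 to 9.319 in the other 3 BD_VNS arrays. BD_VNS 2 stood apart for Casp1, 11.987 against 12.089 to 12.096, for Slc28a2, 10.663 against 11.23 to 11.335, and for Jam2, 7.598 against 7.433 to 7.459. BD_VNS 3 had the highest Socs3, 7.197 against 6.993 to 7.022. Acinar genes in BD as a whole did not stand apart by this measure because 2 of 4 arrays were high.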

How the results depend on the processing

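The tests without BD 4 and BD 6, with the acinar level, with the combined covariate and of opposite signs with split BD arrays were chosen after the result was seen. Of 13015 results for named genes under alternatives, 11413 kept their side of the threshold, 1252 no longer passed, 350 newly passed and 0 reversed. Among the 11413 were 68 whose sign changed while neither value passed; the others kept their direction. The counts of genes were 655 in BD against NBD, 635 in BD_VNS against BD and 965 in BD_VNS against NBD, and moved as follows, in that order. Array weights gave 1642, 1628 and 2599; an adjusted p under 0.10 gave 1036, 1265 and 1545; an absolute log2 fold change of at least 1 gave 30, 16 and 31, the last 2 alternatives by construction. The 3' to 5' ratio as a covariate gave 415 in BD_VNS against BD and 363 in BD_VNS against NBD. Leaving out BD 4 and BD 6 gave 293 in BD against NBD and 152 in BD_VNS against BD, with fewer arrays, and the covariate in addition gave 57 in BD_VNS against BD and 469 in BD_VNS against NBD. The acinar level as a covariate gave 363 in BD against NBD and 338 in BD_VNS against BD, and fitting only the groups compared gave 343 in BD_VNS against BD. Leaving out 1 array in turn gave 317 to 882, 279 to 1108 and 494 to 1638. With the replicate number as a block (replicate block) the counts were 363, 402 and 968, of which 335, 310 and 676 were shared with the fit without it. Deviations of same-numbered arrays from their group means correlated at -0.245 to 0.071. Most of them correlated higher with an array of another number, but the highest of those arrays was taken, which favours that outcome. These correlations therefore do not exclude pairing. The numbers were not treated as pairs because the labels do not say that they pair animals. Of gene lists, 16, 26 and 20 passed; with an estimated correlation 1, 0 and 1 did, and with fry 8, 19 and 8. The correlation between the changes was -0.686; it was -0.415 with the BD arrays split, -0.539 among genes that passed in BD against NBD, -0.429 without BD 4 and BD 6, and -0.206 on average with single BD arrays. In some of the splits BD 4 and BD 6 stood in different comparisons, so their pancreatic transcripts entered the changes with opposite signs. Leaving out 1 array gave correlations of -0.786 to -0.539. Where no construction is named, the cause was not tested. Not run were other pseudocounts, since the table is already log2, and other probe sets of a gene or their median, since each gene has 1.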

Other observations

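The tests of pancreatic tissue, of the intestine's own response, of lower glucocorticoid drive and of the glucocorticoid list without BD 4 and BD 6 were chosen after the result was seen; those of RNA quality and of the gut wall were fixed before it. Some genes of the circadian clock differed from the controls in both groups of brain-dead rats. Per2, a repressor of the clock, fell by 1.03 in BD against NBD (SE 0.13, n = 4 and 3) and by 0.63 in BD_VNS against NBD, and Nr1d1, a nuclear receptor that represses clock genes, rose by 0.41 and 0.42. Cry1, another repressor, fell by 0.59 in BD against NBD. The list of 12 clock genes as a whole did not pass, with 3 members up, 2 down and 7 not past the threshold in each comparison with NBD (adjusted over the list alone, 3 and 3 for BD, 3 and 2 for BD_VNS; camera adjusted p = 0.438 and 0.95).

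Casp1, the protease that activates interleukin-1 beta, rose by 0.64 ± 0.04 (SE) in BD and by 0.63 ± 0.04 in BD_VNS against NBD, and stayed up after stimulation although Il1b did not. Cdkn1a, an inhibitor of the cell cycle, fell by 0.79 and 0.92, and Lyve1, a marker of lymphatic endothelium, by 0.94 and 1.22. The angiotensin receptor gene Agtr1a fell by 0.47 and 0.74. In BD_VNS against NBD, 3 of 12 adipocyte genes fell and 0 rose (adjusted over the list alone, 5 and 0; camera adjusted p = 0.00442, and adjusted p = 0.194 with an estimated correlation), among them Cidec (-0.81 ± 0.08) and the fatty acid carrier gene Fabp4 (-1.09 ± 0.15). Alox5ap, which is needed for leukotriene synthesis, fell by 0.34. Of 12 genes of coagulation and fibrinolysis 4 fell and 0 rose (adjusted over the list alone, 4 and 0; camera adjusted p = 0.000415, and adjusted p = 0.294 with an estimated correlation), with the plasminogen activator genes Plat (-0.86 ± 0.09) and Plau (-0.36 ± 0.05) among them. With the 3' to 5' ratio as a covariate 2 adipocyte and 2 coagulation genes fell, and the list medians went from -0.41 to -0.34 and from -0.09 to -0.06. Plat (-0.47 ± 0.08) and Tfpi, an inhibitor of coagulation (-0.48 ± 0.08), also fell in BD_VNS against BD.

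The pancreatic transcripts in BD 4 and BD 6 could come from pancreatic tissue in these samples. Of 18 acinar genes, 17 lay more than 2 log2 units above the mean of the other 9 arrays in both. The rises in the arrays correlated at 0.963 across the genes. Both rises subtract the same mean of 9 arrays, so part of that correlation is built in. The insulin genes Ins1 (4.71 and 3.14) and Ins2 (4.91 and 3.18) and the islet hormone gene Iapp (1.86 and 0.67), chosen after their values were seen, were higher as well, by amounts that start from low levels and are bounds at most, but the other 6 of 9 islet markers differed by -0.19 to 0.99 in BD 4 and by -0.22 to 0.33 in BD 6. High acinar genes are the pattern itself, so they do not decide for tissue, and the islet markers went different ways. Among those that stayed flat or fell, Slc2a2, Sst and Chga averaged 12.56, 9.53 and 8.945 in the other 9 arrays. A small amount of islet RNA would hardly move such levels, so these markers do not count against tissue. A response common to all BD samples is argued against by BD 1 and BD 3, whose mean acinar level was 0.008 above NBD; a response in only some rats and pancreatic tissue both stay open.

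The fall of glucocorticoid-induced genes might reflect whatever set BD 4 and BD 6 apart, RNA quality or a lower glucocorticoid drive. Without BD 4 and BD 6 the list median was -0.282 in BD against NBD, and with the 3' to 5' ratio as a covariate 7 members still fell, so neither accounts for the whole fall. The list passed in both comparisons with NBD with an estimated correlation (larger limma adjusted p 0.0184), but this fall prompted the explanation and both comparisons share the 3 NBD arrays, so it does not decide for a lower drive. Hormone levels were not analysed here, and a lower drive in brain-dead rats or a raised one in ventilated controls stays open.

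The lower macrophage and matrix genes in BD_VNS than in BD may reflect the make-up of the samples or RNA quality as well as stimulation. The same holds for the inflammatory genes that fell in that comparison. Whether they fell beyond the macrophage and matrix lists was not tested. Less gut wall would lower smooth muscle genes too, yet smooth muscle minus matrix genes rose by 0.47 (2-sided exact permutation p = 0.0286, 70 splits), so a uniform loss is argued against. With the 3' to 5' ratio as a covariate the mean change of 35 members that passed went from -0.639 to -0.511, and 19 still passed. These members were chosen because they passed without the covariate, which favours a change that remains. Over the whole macrophage and matrix lists the medians went from -0.585 to -0.527 and from -0.484 to -0.385. In that fit the ratio does not account for the whole fall. BD_VNS 2, whose ratio was as low as in the controls, showed a smaller change of -0.351 on its own. A loss confined to the mucosa, or fewer cells of these kinds, stays open.

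Chance as the source of the counts of genes was tested by regrouping the same arrays in 35 ways. In BD against NBD, 1 of 35 splits, the real one, gave 655 genes, and the highest other gave 3. In BD_VNS against BD, 1 of 35, again the real one, gave 635, and the highest other gave 1. A rank of 1 of 35 is the best that these splits allow, and every other split mixes the groups compared. Chance is thus argued against for both counts but not excluded. In BD_VNS against NBD, 2 of 35 gave 965 or more, and the highest other, with BD_VNS 2 placed among the NBD arrays, gave 968, so chance cannot be excluded for that count. That split follows the 3' to 5' ratio, which was 1.026 to 1.098 in BD_VNS 1, 3 and 4 and 0.694 to 0.866 in BD_VNS 2 and the NBD arrays, and with the ratio as a covariate the count was 363.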
